A study of Mus musculus with 6 samples.

How the data were processed

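Cardiac cells of Tw2-CreERT2;R26-tdTO mice were obtained by Langendorff perfusion and separated by gravity and a BSA gradient, per the labels' protocols. The non-CM fraction was stained with the dye Mitoview633 and sorted on tdTomato and Mitoview633 fluorescence. Total RNA was extracted from sorted tdTomato-positive (Tw2+) and tdTomato-negative (Tw2-) cells with an RNeasy kit, and libraries were sequenced on an Illumina HiSeq instrument. Single-cell data that the design text also mentions were not analysed here.

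The deposited values are raw counts, 1 whole number per gene symbol and library, for 24062 symbols and 6 libraries. The submitters' processing notes name TopHat2 2.0.0, DESeq2 1.6.3 and the builds GRCm38 and mm10, without saying what each was used for. The counting program, its strand setting, the gene annotation and the strandedness of the libraries are not given in the sources used here. Reads from genes that overlap on opposite strands therefore cannot be separated, and near-identical copies may share reads. Column names gave 4 libraries a group and a replicate number (2 or 3), and 2 libraries a group only. These 2 are called unnumbered, and 0 columns of per-sample values were left unused.

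Total counts ranged from 11746696 to 16447098 per library, and 3 counts in a library corresponded to 0.161 to 0.302 CPM on the TMM-scaled sizes, or to 0.0888 CPM over the 3 Tw2+ libraries, the floor used for Blk. These floors, the bound given for Blk and the Poisson interval given for Twist2 cover counting error only. The 20 most abundant genes took 10.5% to 17.0% of the counts of a library. Every pair of libraries of a group differed by more than sampling noise (chi-square per degree of freedom of at least 27.3 over genes), so no library was counted more than once. The p-values measure the spread between libraries described as biological replicates. No sequencing batch or date is given in the sources used here.

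Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test (glmQLFit and glmQLFTest) on all 6 libraries with TMM factors, which lay between 0.846 and 1.13. Genes were filtered with filterByExpr at a minimum count of 10, which left 13180 genes, and 5846 symbols had no count in any library. The p-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. CPM values use TMM-scaled library sizes, and all log2 fold changes are Tw2+ over Tw2-. Principal components were computed on log2 CPM with a prior count of 2.

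Before the data were examined, 33 gene lists were fixed, 15 of cell type markers and 18 of pathways. Each list is given with its count of members past the test over all genes and with the count adjusted over the list alone. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. A further 10 lists, described in the closing section, were chosen after the data were seen, and leave out some genes whose values had been seen by then. Every listed gene had an entry in the table, Adgre1 under the symbol Emr1 and C1s under the symbol C1s1.

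The genes named were set by a rule fixed in advance. It takes Twist2 and Twist1, then the 10 largest increases and the 10 largest decreases among called genes with an average of at least 10 CPM, no overlap between the groups and a gene name other than a model number. From each list it takes up to 4 tested members, 2 by the smallest adjusted p and 2 by the highest level. Some genes that the rule takes are not reported here. Emcn, Cdh5, Reln, Plod2, Bmp4, Vegfc, Pdgfb, Pdgfc, Angpt2, C5ar1, Ifi44, Rsad2, Atf3, Il6, Il33, Ereg, Lif, Il11 and Chac1 lie outside this rule and were named after their values were seen, as were the members of the 10 later lists.

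Gene positions, exonic overlaps, lengths and GC content came from GENCODE M21 on GRCm38, which matched 23665 of the 24062 symbols (98.4%). Of the 139 genes whose values are given, 12 share at least 10% of their exonic length with another gene, 1 of them on the same strand.

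Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and library-size scaling, no filter on low counts, a filter of at least 50 counts in 3 libraries, an adjusted p under 0.01, removal of the 20 most abundant genes, robust dispersion, the replicate number as a block, and each library left out in turn. Scaling to the 13 fibroblast markers, an offset per library for GC content and gene length (splines with 5 degrees of freedom), and a fit without both Tw2+ 3 and the unnumbered Tw2- library were added after the data were seen. No test of outlying libraries was made, since groups of 3 are too small for one.

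The tests were tried on simulated counts of 13024 genes with the means and library sizes of the Tw2+ against Tw2- comparison. The changed genes were drawn only from genes with mean counts well above the filter's minimum, so recovery of low-count genes was not tested. Of 100 genes changed 2-fold edgeR recovered 19%, and of 100 changed 4-fold it recovered 89%, with 4 false calls among 112. DESeq2 recovered 42% and 95%, with 31 false calls among 168. Camera called 2 of 2 changed lists and 0 of 30 unchanged ones. The simulated genes varied independently of each other, so this result does not test camera on lists whose members move together. Figures were drawn with matplotlib 3.10.9.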

Results

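Non-cardiomyocytes (non-CMs) of the adult mouse heart were compared by bulk RNA sequencing according to whether they had been marked by a Twist2 driver. Twist2 is a basic helix-loop-helix transcription factor of mesenchymal cells. In Tw2-CreERT2;R26-tdTO mice, tamoxifen lets a Cre recombinase made in Twist2-expressing cells switch on the red fluorescent protein tdTomato permanently, so that a tdTomato-positive cell expressed the driver at the time of dosing or descends from one that did. Tamoxifen was given at 8 weeks of age and cells were taken 10 days after the first dose, with mice recorded as 9 weeks old. Sorted tdTomato-positive cells (Tw2+) and tdTomato-negative cells (Tw2-) gave 3 libraries each, which the design text calls biological replicates. How many hearts went into a library is not given in the sources used here. In each group, 1 library is called unnumbered here because its column carries no replicate number. Total counts were 15156873 in Tw2- 2, 16447098 in Tw2- 3 and 11767130 in the unnumbered Tw2- library. Among the Tw2+ libraries they were 13280522 in Tw2+ 2, 12190199 in Tw2+ 3 and 11746696 in the unnumbered one.

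The groups lay on opposite sides of the first principal component, which held 77.3% of the variance of log2 CPM, the read counts scaled by library size. The Tw2+ libraries had scores of 72.2 (Tw2+ 2), 27.9 (Tw2+ 3) and 95.5 (unnumbered), and the Tw2- libraries had scores of -69.2 (Tw2- 2), -80.2 (Tw2- 3) and -46.1 (unnumbered). Tw2+ 3 and the unnumbered Tw2- library were thus the closest pair across the groups on this axis. The biological coefficient of variation between libraries of a group was 27.6%.

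Twist2 itself was measured first, since the sort rests on its promoter. Its transcript averaged 6.93 ± 0.421 CPM in Tw2+ and 3.50 ± 1.48 CPM in Tw2- (mean ± SD, n = 3 libraries each). The values were 7.35, 6.50 and 6.95 CPM in Tw2+ 2, Tw2+ 3 and the unnumbered Tw2+ library, from 85, 80 and 69 counts. They were 2.41, 2.90 and 5.18 CPM in Tw2- 2, Tw2- 3 and the unnumbered Tw2- library, from 40, 54 and 66 counts. All 3 Tw2+ libraries lay above all 3 Tw2- libraries, and the log2 fold change was 1.00 (SE 0.34) with an adjusted p of 0.0738 in edgeR's quasi-likelihood test, so the difference did not pass that test, while it passed in DESeq2 (1.00, adjusted p = 0.0333). Without the unnumbered Tw2- library the log2 fold change was 1.33 at an adjusted p of 0.0365, and relative to the 13 fibroblast markers, a scaling chosen after the data were seen, it was 0.46 at an adjusted p of 0.294. Twist2 lies on chromosome 1 at 91801461 to 91848028 of GRCm38, on the + strand, with 2 exons. The antisense gene Gm29100 overlaps 1477 bp, or 46.5%, of its exonic length, and since the strand setting of the counting is not known, reads of these genes cannot be separated. Twist1, its close relative, averaged 23.0 ± 3.04 CPM in Tw2+ and 14.7 ± 3.89 CPM in Tw2-, a log2 fold change of 0.65 (SE 0.25) that did not pass the test either (adjusted p = 0.0970).

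Across the transcriptome, 2395 of 13180 tested genes (18.2%) differed between the populations at an adjusted p under 0.05 in edgeR. Of these, 976 were higher and 1419 lower in Tw2+, and 698 and 1277 of them differed by at least 2-fold. The groups' CPM values did not overlap for 96.6% of the called genes and for 37.4% of all tested genes, where 10% would do so by chance with 3 libraries against 3. An unadjusted p under 0.05 was reached by 4842 genes. The count of higher genes depended on single libraries. It was 390 without Tw2- 2, 81 without Tw2- 3, 300 without the unnumbered Tw2- library, 187 without Tw2+ 2, 2801 without Tw2+ 3 and 227 without the unnumbered Tw2+ library. The corresponding counts of lower genes were 861, 811, 1416, 824, 2906 and 885. Log2 fold changes are given on the scale of TMM normalisation. Scaling by library size alone shifted the median of all genes by -0.28 and put 80.9% of the calls on the lower side, against 59.2% with TMM. Scaling to the fibroblast markers shifted the median by -0.60 and put 96.7% there, with 116 genes higher, 110 of them by at least 2-fold.

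The 10 genes with the largest increases in Tw2+, among the called genes that met the naming rule, included genes of secreted factors and of matrix. That rule requires an average of at least 10 CPM, no overlap between the groups and a gene name other than a model number. Dok5, an adaptor of receptor tyrosine kinases, averaged 59.4 ± 48.3 CPM in Tw2+ and 3.10 ± 1.46 CPM in Tw2- (log2 fold change 4.27, SE 0.68, adjusted p = 0.00374). Tnfrsf11b, the decoy receptor osteoprotegerin, was 10.0-fold higher (log2 3.33, SE 0.45, adjusted p = 0.00161). The matrix glycoprotein Tnc was 8.47-fold higher (log2 3.08, SE 0.71, adjusted p = 0.0208). Csf1, the growth factor of macrophages, reached 7948 ± 5103 CPM in Tw2+ against 961 ± 484 CPM in Tw2- (log2 3.05, SE 0.58, adjusted p = 0.00920). Inhba, a subunit of activin A, rose 8.04-fold from 12.7 to 102 CPM (log2 3.01, SE 0.44, adjusted p = 0.00255). The other genes among the 10 with the largest increases were Baiap2l1, Nptx2, Cda, Asb5 and Cgref1, with log2 fold changes from 3.03 to 3.58. With 1 library left out at a time, Dok5, Tnfrsf11b, Csf1, Inhba, Baiap2l1, Nptx2 and Cda passed the test in all 6 fits, Asb5 in 5, and Tnc and Cgref1 in 4. Tw2+ 3 had the lowest Tw2+ value of each of the 10. The mean log2 CPM of all genes called higher by at least 2-fold was 4.98 there, against 5.85 in Tw2+ 2 and 6.21 in the unnumbered Tw2+ library, and from 3.91 to 4.40 in Tw2-.

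**Figure D1:**
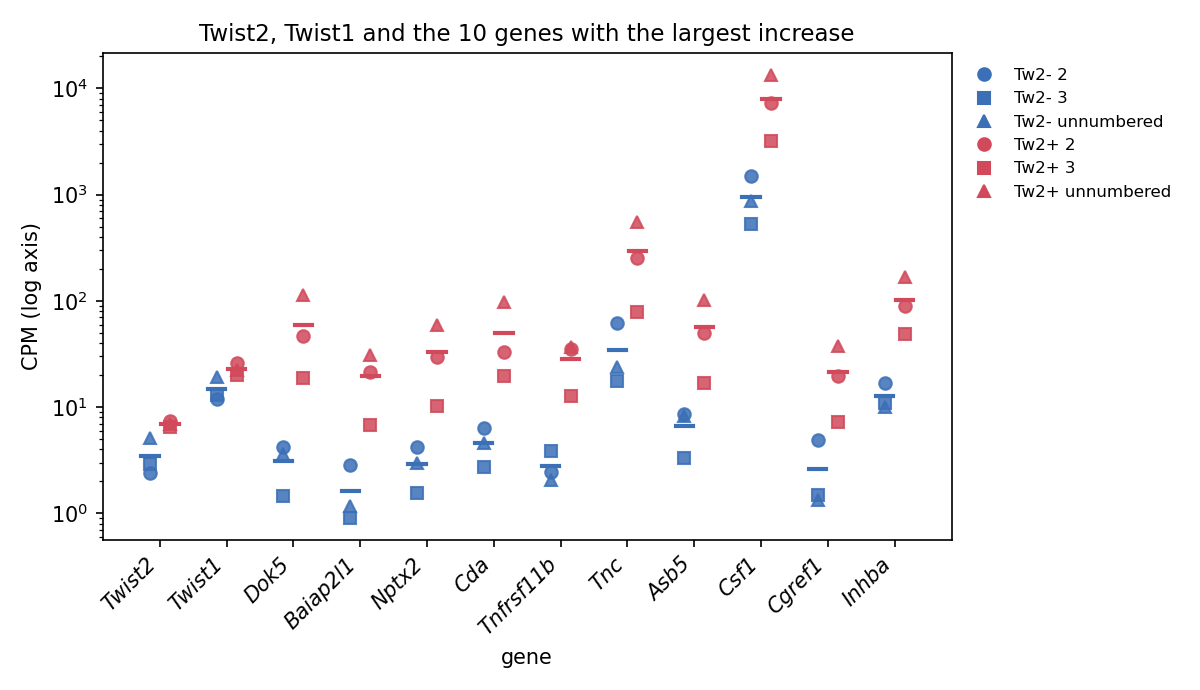
CPM on a log axis of Twist2, Twist1 and the 10 genes with the largest increase in Tw2+, with 1 point per library and a bar at the mean of each group's 3 libraries. For each gene the 3 Tw2+ points lie above the 3 Tw2- points, from 18.8 to 113 CPM against 1.45 to 4.22 CPM for Dok5. For the 10 genes this separation was a condition of their choice.

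The 10 genes with the largest decreases, chosen by the same rule, included markers of granulocytes and of erythroid cells. Csf3r, the receptor of granulocyte colony-stimulating factor, averaged 0.607 ± 0.205 CPM in Tw2+ and 82.1 ± 6.79 CPM in Tw2-, a log2 fold change of -7.03 (SE 0.29, adjusted p = 2.49e-05). S100a9 and S100a8, the calprotectin subunits of neutrophils and monocytes, were at -7.33 (SE 0.62) and -7.00 (SE 0.70). Alas2, the haem synthesis enzyme of erythroid cells, had 0.240 CPM in Tw2+ and 61.2 CPM in Tw2- (log2 -7.96, SE 0.64, adjusted p = 0.000188). Il1b, the inflammatory cytokine, fell from 148 to 3.06 CPM (log2 -5.58, SE 0.37, adjusted p = 0.000127). Slfn4, Hcar2, Cytip, Cyp4f18 and Wdfy4 completed the 10 genes, with log2 fold changes from -7.85 to -5.37. All 10 passed the test in each of the 6 fits with 1 library left out. Antisense Apex2 overlaps 12.9% of the exonic length of Alas2.

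Leukocyte markers were lower in Tw2+ for each list that could be tested. All 14 macrophage and monocyte markers fell, with a median log2 fold change of -4.37. Csf1r, the receptor of Csf1, dropped 20.6-fold from 606 to 29.4 CPM (log2 -4.36, SE 0.45, adjusted p = 0.000357), and Lyz2, the lysozyme of myeloid cells, dropped from 1247 to 58.9 CPM (log2 -4.40, SE 0.47, adjusted p = 0.000443). Antisense Hmgxb3 overlaps 15.1% of the exonic length of Csf1r. The endosomal glycoprotein Cd68 fell by 3.50 on the log2 scale. All 6 granulocyte markers fell, Mmp9 the least of them at -3.75, with a list median of -7.18. With 2 members without a Tw2+ count set at 3 counts over the group, the median was -7.02. All 6 B cell markers fell, with a median of -4.63. The antigen receptor component Cd79a was at -2.73 (SE 0.40, adjusted p = 0.00241). The kinase Blk had 0 counts in Tw2+ and 155 in Tw2-. With 3 counts over the group as the floor it was 36.4-fold lower, and the lower 95% bound for counting error was 29.3-fold. The camera test of limma, with a preset correlation, placed these lists lower at adjusted p of 2.38e-13, 5.57e-08 and 3.85e-07. With an estimated correlation the adjusted p was 0.372 for each of the 3 lists, while the fry test placed them lower at 0.00561, 0.00108 and 0.000487. The counts adjusted over the list alone were the same 14, 6 and 6. Of 8 T and NK cell markers 2 were tested, and 1 fell over all genes, while both passed when adjusted over the list alone. Of 6 erythroid markers only Alas2 was tested. None of 5 adipocyte markers reached the count minimum.

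Markers of vascular endothelium were lower in Tw2+ as a list, but differed between libraries of a group. All 14 were fitted below 0 (median log2 fold change -2.19), 4 passed the test over all genes, and 13 passed when adjusted over the list alone. The 4 were Egfl7 (log2 -2.53, SE 0.66, adjusted p = 0.0325), the VEGF receptor Kdr (-2.58, adjusted p = 0.0446), the sialomucin Emcn (-2.45, adjusted p = 0.0466) and VE-cadherin, Cdh5 (-2.44, adjusted p = 0.0497). Tek, the angiopoietin receptor, was at -0.30 (adjusted p = 0.335). The mean log2 CPM of the 14 markers was 6.21 in Tw2+ 3 against 4.55 in Tw2+ 2 and 4.03 in the unnumbered Tw2+ library, and 5.85 in the unnumbered Tw2- library against 7.69 in Tw2- 2 and 7.63 in Tw2- 3. Without Tw2+ 3, 13 of the 14 passed over all genes, and without the unnumbered Tw2- library 11 passed. With any other library left out, 0 of the 14 passed in edgeR. On all 6 libraries DESeq2 called 10 lower, limma-voom 6 and edgeR without the filter on low counts 13. The list was lower in camera at an adjusted p of 0.000254 (adjusted p = 0.598 with an estimated correlation and 0.132 in the fry test).

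Lymphatic endothelial markers were lower in Tw2+ as well. Of 6 listed, 5 were tested and 4 fell, both over all genes and adjusted over the list alone. The hyaluronan receptor Lyve1, which is also found on tissue macrophages, fell from 212 to 13.4 CPM (log2 -3.97, SE 0.46, adjusted p = 0.000667). Mmrn1 was at -5.40 (adjusted p = 0.00197), Reln at -4.33 (adjusted p = 0.0185) and the VEGF-C receptor Flt4 at -1.97 (adjusted p = 0.0418), while the transcription factor Prox1 was at -0.016 (adjusted p = 0.981). Lyve1 and Mmrn1 passed in all 6 fits with 1 library left out. The number of members past the test was 2 without Tw2- 2, Tw2+ 2 or the unnumbered Tw2+ library. The list was lower in camera at an adjusted p of 0.0109 (0.0517 without Tw2+ 3, 0.0569 with scaling to the fibroblast markers). The adjusted p was 0.458 with an estimated correlation and 0.0395 in fry. Among 5 endocardial markers the transcription factor Nfatc1 rose (log2 1.29, SE 0.39, adjusted p = 0.0491) and Plvap fell (-1.73, adjusted p = 0.0491). The list median was -1.60 and the adjusted p in camera 0.337, and over the list alone 1 was higher and 3 lower. Nfatc1 passed in 1 and Plvap in 2 of the 6 fits with 1 library left out.

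Fibroblast markers leaned higher in Tw2+, with 1 past the test. Of 13 markers, 12 were fitted above 0 with a median log2 fold change of 0.58, and 1, the epicardial and fibroblast transcription factor Tcf21, rose past the test over all genes (log2 1.14, SE 0.30, adjusted p = 0.0332). Adjusted over the list alone, 5 were higher. Dcn, which encodes the proteoglycan decorin, was at 12151 ± 914 CPM in Tw2+ and 8216 ± 1988 CPM in Tw2-, a difference that did not pass (log2 0.56, SE 0.31, adjusted p = 0.212). Serpinf1 was at 0.66 (adjusted p = 0.0630) and the collagen gene Col3a1 at -0.18 (adjusted p = 0.648). The list was higher in camera at an adjusted p of 0.00138 (adjusted p = 0.595 with an estimated correlation and 0.0857 in fry). Without Tw2+ 3, 6 markers passed over all genes. Without the unnumbered Tw2- library 1 passed, and with any other library left out, 0 passed in edgeR. On all 6 libraries DESeq2 called 6 of the 13 higher and limma-voom 1.

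The pericyte and smooth muscle lists did not pass. Of 9 pericyte markers, 8 were fitted below 0, and 1 passed, over all genes as well as over the list alone. This was the PDGF receptor Pdgfrb, which rose from 255 to 459 CPM (log2 0.84, SE 0.22, adjusted p = 0.0344). The regulator of G protein signalling Rgs5 was at -1.44 (adjusted p = 0.143). Of 7 tested smooth muscle markers, the contractile genes Myh11 (log2 -1.66, SE 0.42, adjusted p = 0.0303) and Mylk (-1.77, SE 0.49, adjusted p = 0.0390) fell, and over the list alone 1 was higher and 2 lower. The camera adjusted p was 0.347 for the pericyte and 0.605 for the smooth muscle list. Without the unnumbered Tw2- library the pericyte list was lower at an adjusted p of 0.0281, and 2 pericyte markers fell without that library or without Tw2+ 3. Pdgfrb passed in 1 of the 6 fits with 1 library left out, and Myh11 and Mylk in 2 each.

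Cardiomyocyte transcripts, which were detected in both groups of sorted non-CMs, were lower in Tw2+. All 14 markers fell, over all genes and over the list alone, with a median log2 fold change of -2.01. The heavy chain of cardiac myosin, Myh6, had 92.5 ± 51.9 CPM in Tw2+ and 320 ± 111 CPM in Tw2- (log2 -1.79, SE 0.44, adjusted p = 0.0273). The natriuretic peptide gene Nppa fell by 3.18 and myoglobin, Mb, fell by 2.09 on the log2 scale. Antisense genes overlap 61.5% of the exonic length of Nppa and 27.6% of that of Mb. Camera placed the list lower at an adjusted p of 3.85e-07 (adjusted p = 0.458 with an estimated correlation and 0.0395 in fry). Without Tw2- 2 or the unnumbered Tw2- library, 8 of the 14 passed in edgeR.

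Epicardial and Schwann cell lists did not pass. None of 8 epicardial and mesothelial markers passed in edgeR over all genes or over the list alone, and Tbx18, an epicardial transcription factor, came nearest (log2 0.69, SE 0.21, adjusted p = 0.0544, with 20.6% of its exonic length under an overlapping model on the opposite strand). The list median was -0.04, and camera gave an adjusted p of 0.987. The list's mean log2 CPM was 4.40 in Tw2+ 3, 1.82 in Tw2+ 2 and 0.805 in the unnumbered Tw2+ library. Without Tw2+ 3 the median was -2.47, with 1 marker higher and 3 lower, and without the unnumbered Tw2- library 1 was higher. The median was 0.78 without Tw2- 2, 0.41 without Tw2+ 2 and 0.45 without the unnumbered Tw2+ library. Of 3 tested Schwann cell markers the myelin gene Mbp fell (log2 -2.41, SE 0.57, adjusted p = 0.0234) and the list's camera adjusted p was 0.605. Mbp passed in 3 of the 6 fits with 1 library left out.

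**Figure D2:**
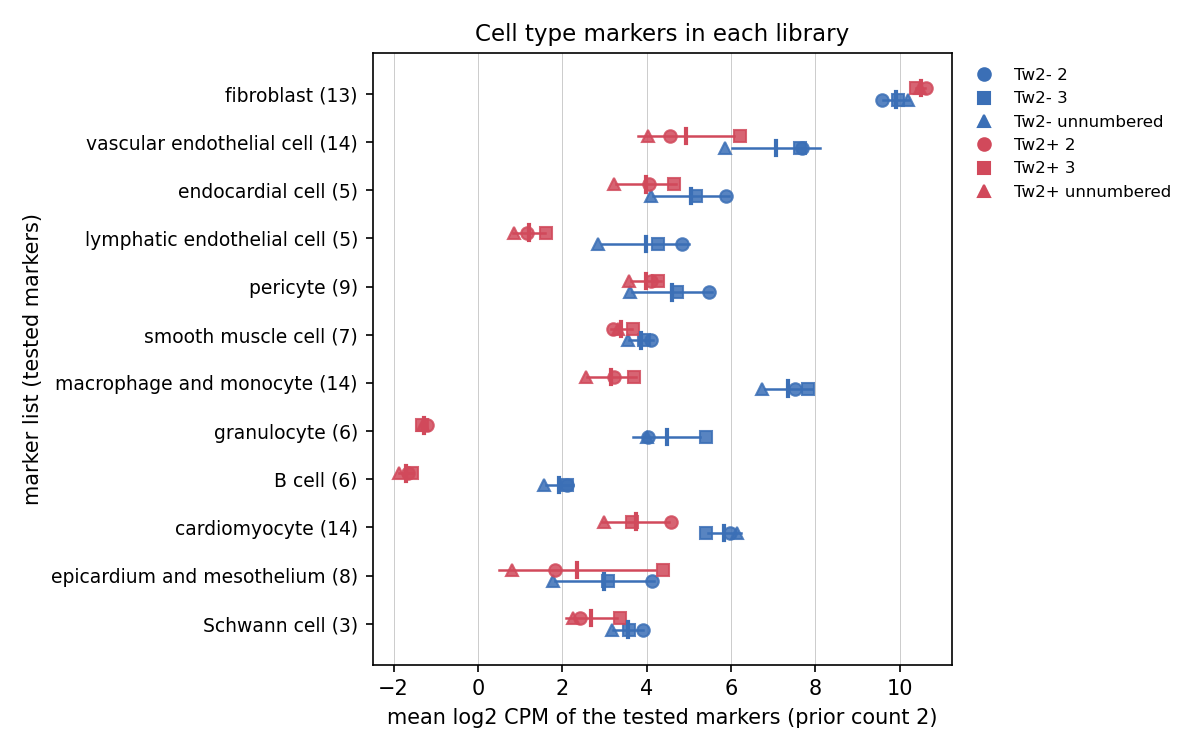
Mean log2 CPM (prior count 2) of the tested markers of each cell type list with at least 3 tested members, with 1 point per library, a tick at the mean and a line for ± 1 SD of each group's 3 libraries. The macrophage points lie between 2.56 and 3.71 in Tw2+ and between 6.73 and 7.83 in Tw2-, while for vascular endothelium Tw2+ 3 (6.21) lies above the unnumbered Tw2- library (5.85).

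The matrix lists leaned higher in Tw2+ with TMM, with few members past the test, but not relative to the fibroblast markers, where the medians of both matrix lists were negative (-0.22 and -0.15). The median of all tested genes on that scale was -0.59. Of 19 extracellular matrix genes beyond the fibroblast markers, 17 were fitted above 0 with a median log2 fold change of 0.32, and the collagen genes Col5a2 (log2 0.92, SE 0.23, adjusted p = 0.0277) and Col8a1 (0.78, SE 0.22, adjusted p = 0.0427) rose. Adjusted over the list alone, 0 of the 19 passed in edgeR. The proteoglycan gene Bgn was at 0.95 (adjusted p = 0.0577). Of 14 matrix remodelling genes, all were fitted above 0 (median 0.42) and 3 rose, or 4 when adjusted over the list alone. Lox, the collagen-crosslinking lysyl oxidase, rose 3.47-fold from 144 to 499 CPM (log2 1.80, SE 0.29, adjusted p = 0.00410), the metalloproteinase inhibitor Timp1 rose by 2.10 (adjusted p = 0.0173) and the lysyl hydroxylase Plod2 by 0.65 (adjusted p = 0.0347). Both lists were higher in camera, at adjusted p of 0.00264 and 0.00110, while with an estimated correlation the adjusted p was 0.698 and 0.458, and in fry 0.138 and 0.0395. Without Tw2+ 3, 4 genes of each list passed. With any other library left out, 0 of the 19 matrix genes passed, and 1 remodelling gene passed without Tw2- 3 or Tw2+ 2. Lox passed in all 6 fits with 1 library left out.

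Of 9 genes of activated fibroblasts, Tnc and Ltbp2 rose over all genes and 2 passed over the list alone. Ltbp2, a latent TGF-beta binding protein, had a log2 fold change of 0.92 (SE 0.27, adjusted p = 0.0457). Postn, which encodes periostin, averaged 356 ± 110 CPM in Tw2+ and 179 ± 131 CPM in Tw2- and did not pass (log2 0.99, SE 0.47, adjusted p = 0.161). The list median was 0.60, or -0.04 relative to the fibroblast markers. The list was higher in camera at an adjusted p of 0.0401, which was 0.0780 without the unnumbered Tw2- library, 0.0764 without Tw2+ 2, 0.0589 without Tw2+ 3, 0.458 with an estimated correlation and 0.124 in fry. Without Tw2- 3 or the unnumbered Tw2- library 0 of the 9 passed in edgeR, without Tw2+ 2 1 passed, and without Tw2+ 3 4 passed.

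The list of TGF-beta and BMP signalling genes leaned higher in Tw2+ with TMM, with few members past the test. The list also holds receptors and signal transducers, while the genes named here are ligands. Of 18 genes, 15 were fitted above 0 (median log2 fold change 0.61), 4 rose over all genes and 5 over the list alone. Tgfb2, a TGF-beta ligand, rose 5.17-fold from 47.0 ± 3.51 to 243 ± 96.5 CPM (log2 2.37, SE 0.31, adjusted p = 0.00137). Bmp2 rose by 1.17 (adjusted p = 0.00371) and Bmp4 by 0.97 (adjusted p = 0.0136). The list was higher in camera at an adjusted p of 0.00106 (adjusted p = 0.372 with an estimated correlation and 0.0116 in fry). Relative to the fibroblast markers the median was 0.01, and 2 members were higher and 1 lower. Tgfb2 and Bmp2 passed in all 6 fits with 1 library left out, and Bmp4 in 4. The number of members that rose was 2 without Tw2- 3 and 9 without Tw2+ 3, where 1 fell.

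Regulators of mesenchymal transition did not pass as a list in camera (adjusted p = 0.239) or fry (adjusted p = 0.223), though they did in its mixed test, which lets members go either way (adjusted p = 0.00761, median log2 fold change 0.44, or -0.08 relative to the fibroblast markers). Of 9 tested, the forkhead factor Foxc2 rose 6.72-fold from 22.4 to 151 CPM (log2 2.75, SE 0.44, adjusted p = 0.00412) and the zinc finger repressor Zeb2 fell (-0.62, SE 0.18, adjusted p = 0.0441). Over the list alone 1 was higher and 1 lower. The intermediate filament gene Vim was at 0.80 (adjusted p = 0.0765). Foxc2 passed in all 6 fits with 1 library left out and Zeb2 in 1, and without Tw2+ 3 the list held 3 genes that rose.

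The series title speaks of a multi-potent population. Cardiac transcription factors and progenitor markers were listed with that wording in mind, but bulk RNA does not show what the marked cells can give rise to. Of 10 tested cardiac transcription factors 0 rose, and Hopx (log2 -2.10, SE 0.36, adjusted p = 0.00572) and Mef2c (-1.73, SE 0.31, adjusted p = 0.00655) fell, over all genes and over the list alone, and in all 6 fits with 1 library left out. Antisense Hopxos overlaps 27.2% of the exonic length of Hopx. Gata4 was at 0.49 (adjusted p = 0.107), or -0.077 relative to the fibroblast markers. In the same libraries the medians of the cardiomyocyte (-2.01), vascular endothelial (-2.19) and macrophage markers (-4.37) fell, and bulk counts do not show in which cells Hopx and Mef2c were lower. The list's camera adjusted p was 0.251 with a median of -0.25. Of 10 progenitor markers 0 passed in edgeR over all genes or over the list alone, and the camera adjusted p was 0.605. The receptor Kit was at -1.02 (adjusted p = 0.132), the hyaluronan receptor Cd44 at 0.91 (adjusted p = 0.214), Cd34 at 0.42 (adjusted p = 0.271) and Klf4 at 0.32 (adjusted p = 0.372). The median of the 10 was 0.30, or -0.30 relative to the fibroblast markers, where Cd34 and Klf4 turned to -0.13 and -0.30. Without Tw2+ 3, 1 progenitor marker was higher and 1 lower.

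The Notch list was lower in Tw2+, with 1 member past the test. Of 12 genes 11 were fitted below 0 (median log2 fold change -0.94), and the Notch target Hey1 fell (log2 -1.61, SE 0.40, adjusted p = 0.0271). Over the list alone 1 fell as well. The ligand Dll4 averaged 12.1 ± 10.8 CPM in Tw2+ and 48.7 ± 29.0 CPM in Tw2- and did not pass (adjusted p = 0.0710). The list was lower in camera at an adjusted p of 0.0296, which was 0.0950 without Tw2- 2, 0.0567 without Tw2+ 2, 0.0583 with library size alone, 0.117 relative to the fibroblast markers, 0.458 with an estimated correlation and 0.0676 in fry. Without Tw2+ 3, 8 genes fell and 1 rose, without the unnumbered Tw2- library 3 fell, and with any other library left out, 0 passed in edgeR. DESeq2 called 4 lower on all 6 libraries. The list's mean log2 CPM was 5.08 in Tw2+ 3 against 4.30 in Tw2+ 2 and 4.18 in the unnumbered Tw2+ library, and 5.05 in the unnumbered Tw2- library against 5.77 in Tw2- 2 and 5.63 in Tw2- 3, so the libraries that stood apart were those that did so in the vascular endothelial markers, whose median fell by 2.19. Of 12 tested Wnt genes, the receptor Fzd1 rose (log2 0.76, SE 0.19, adjusted p = 0.0282), in 1 of the 6 fits with 1 library left out. The Wnt list had a camera adjusted p of 0.521 and a median of 0.13, which was -0.14 with library size alone, -0.43 relative to the fibroblast markers, -0.04 without Tw2- 2 and -0.12 without Tw2+ 3.

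Growth factors went both ways. Of 16 genes 4 rose and 3 fell, or 5 and 4 over the list alone, with a median log2 fold change of -0.47 and a camera adjusted p of 0.987. The fibroblast growth factor Fgf2 rose 7.25-fold (log2 2.86, SE 0.49, adjusted p = 0.00580). Vegfa, the main growth factor of blood vessels, rose from 256 to 1292 CPM (log2 2.34, SE 0.45, adjusted p = 0.00947), and the lymphatic growth factor Vegfc rose by 1.07 (adjusted p = 0.0136). Pdgfb (log2 -3.10, SE 0.68, adjusted p = 0.0179), Pdgfc (-2.86, adjusted p = 0.0102) and the angiopoietin Angpt2 (-1.69, adjusted p = 0.0443) fell. Vascular endothelial (median -2.19) and macrophage markers (-4.37) fell in the same libraries, and bulk counts do not show in which cells these growth factors were lower. Fgf2, Vegfa and Pdgfc passed in all 6 fits with 1 library left out, Vegfc in 4, Pdgfb in 3 and Angpt2 in 2. The number of growth factors that fell was 1 without Tw2- 2, Tw2- 3 or Tw2+ 2.

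Chemokines and cytokines also went both ways, with 7 of 15 genes lower and 3 higher in Tw2+, or 8 and 5 over the list alone. Ccl3, a chemokine of myeloid cells, fell from 205 ± 16.9 to 9.90 ± 2.85 CPM (log2 -4.36, SE 0.26, adjusted p = 0.000127), and Ccl4 fell by 4.19. The macrophage (median -4.37) and granulocyte markers (-7.18) fell in the same libraries, and bulk counts do not show whether fewer such cells account for these falls. The neutrophil chemokine Cxcl1 rose from 457 to 1519 CPM (log2 1.73, SE 0.37, adjusted p = 0.0167), the cytokine Il6 by 1.75 (adjusted p = 0.0198) and Il33 by 1.11 (adjusted p = 0.0323). Ccl2 was at 1.68 (adjusted p = 0.0739). The list was lower in camera at an adjusted p of 0.0401 with a median of -1.03. That adjusted p was 0.0608 without Tw2- 2, 0.0561 without the unnumbered Tw2- library, 0.247 without Tw2+ 3, 0.0752 with upper-quartile factors, 0.193 with library size alone, 0.244 relative to the fibroblast markers, 0.0772 with the offset for GC content and length, and 0.372 with an estimated correlation. Fry placed the list lower at an adjusted p of 0.000572. The number of genes that rose was 5 without Tw2+ 3, 0 without Tw2- 3 and 1 without any of the other 4 libraries. Relative to the fibroblast markers 0 were higher in edgeR.

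Antigen presentation, complement and interferon genes were lower where they differed. All 7 MHC class II genes fell, over all genes and over the list alone, with a median log2 fold change of -4.95. The invariant chain Cd74 fell from 2414 to 78.0 CPM (log2 -4.95, SE 0.57, adjusted p = 0.000643) and the class II chains H2-Eb1 and H2-Aa were at -5.20 and -5.05. Medians of macrophage (-4.37), B cell (-4.63) and granulocyte markers (-7.18) lay as low or nearly so, and bulk counts do not show whether fewer such cells or lower levels within cells account for the falls. In camera the list was lower at an adjusted p of 3.07e-07 (adjusted p = 0.372 with an estimated correlation and 0.00821 in fry). Of 12 complement genes, 3 fell, over all genes and over the list alone. They were properdin, Cfp (log2 -2.26, SE 0.21, adjusted p = 0.000241), and the anaphylatoxin receptors C3ar1 and C5ar1 (-4.25 and -4.24). The complement component C3 was at -0.12 (adjusted p = 0.749). The list's camera adjusted p was 0.262, while fry placed it lower at an adjusted p of 0.0395. Without the unnumbered Tw2- library 5 complement genes fell. Of 12 interferon-induced genes 4 fell, over all genes and over the list alone, among them Mx1 (log2 -2.58, SE 0.30, adjusted p = 0.000686), Ifi44 (-1.77, adjusted p = 0.0346) and Rsad2 (-1.38, adjusted p = 0.0471). The list's camera adjusted p was 0.251. Mx1 passed in all 6 fits with 1 library left out, and Ifi44 and Rsad2 in 2. Without Tw2- 2, Tw2- 3, Tw2+ 2 or the unnumbered Tw2+ library 1 interferon-induced gene fell, and without Tw2- 2 another rose.

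Cell cycle genes were lower in Tw2+, as were the markers of leukocytes. Of 14 tested genes 7 fell and 0 rose over all genes, and 10 fell over the list alone, with a median log2 fold change of -1.22. The proliferation marker Mki67 fell 10.2-fold from 30.2 to 2.94 CPM (log2 -3.35, SE 0.34, adjusted p = 0.000353), the topoisomerase gene Top2a fell by 2.34 (adjusted p = 0.00207) and Mcm5, of the replication helicase, fell by 1.43 (adjusted p = 0.00774). These 3 passed in all 6 fits with 1 library left out. The 14 macrophage, 6 granulocyte and 6 B cell markers fell in the same libraries, and bulk counts do not show whether the marked cells cycled less or Tw2- held more cycling cells of other types. Camera placed the list lower at an adjusted p of 3.99e-05 (adjusted p = 0.372 with an estimated correlation and 0.00903 in fry).

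Immediate early and dissociation stress genes differed between libraries of the Tw2+ group. Of 17 genes 3 fell over all genes, and over the list alone 1 was higher and 3 lower. The heat shock gene Hspa1a fell from 2450 to 641 CPM (log2 -1.93, SE 0.31, adjusted p = 0.00371), Hspa1b fell by 1.47 (adjusted p = 0.0210) and the stress factor Atf3 fell by 0.86 (adjusted p = 0.0498). Hspa1a and Hspa1b are near-identical copies, so the split of reads between them is uncertain, and antisense Gm20481 overlaps 19.0% of the exonic length of Hspa1a. The mean log2 CPM of the 17 genes was 10.8 in Tw2+ 3, 9.65 in Tw2+ 2 and 9.67 in the unnumbered Tw2+ library, and 10.5, 10.9 and 10.6 in Tw2- 2, Tw2- 3 and the unnumbered Tw2- library. The list median was -0.63 and the camera adjusted p 0.102, while without Tw2+ 3 it was lower at 0.00239, with 9 genes lower and 2 higher. Without Tw2- 2, Tw2- 3, Tw2+ 2 or the unnumbered Tw2+ library 1 gene fell, and Hspa1a passed in all 6 fits.

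Of 14 nuclear genes of oxidative phosphorylation, 0 passed in edgeR over all genes or over the list alone (median log2 fold change -0.08, camera adjusted p = 0.735). The succinate dehydrogenase subunit Sdha was at -0.58 (adjusted p = 0.0647). With library size alone 2 of the 14 fell and relative to the fibroblast markers 6 fell, and without Tw2+ 3 1 fell. Of 10 genes of endothelial lipid handling, the nuclear receptor Pparg (log2 -2.38, SE 0.56, adjusted p = 0.0222) and the lipoprotein lipase anchor Gpihbp1 (-2.36, SE 0.67, adjusted p = 0.0431) fell, and 6 fell over the list alone. The vascular endothelial markers fell in the same libraries (median -2.19), and as with them, the list's mean log2 CPM in Tw2+ 3 (5.20) lay above that in the unnumbered Tw2- library (5.14). The list median was -1.34 and its camera adjusted p 0.0614, which was 0.0259 without the unnumbered Tw2- library, 0.0446 with no filter on low counts and 0.0467 with the offset for GC content and length. Without Tw2+ 3, 6 fell and 1 rose, and without the unnumbered Tw2- library 5 fell. With any other library left out, 0 passed in edgeR.

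**Figure D3:**
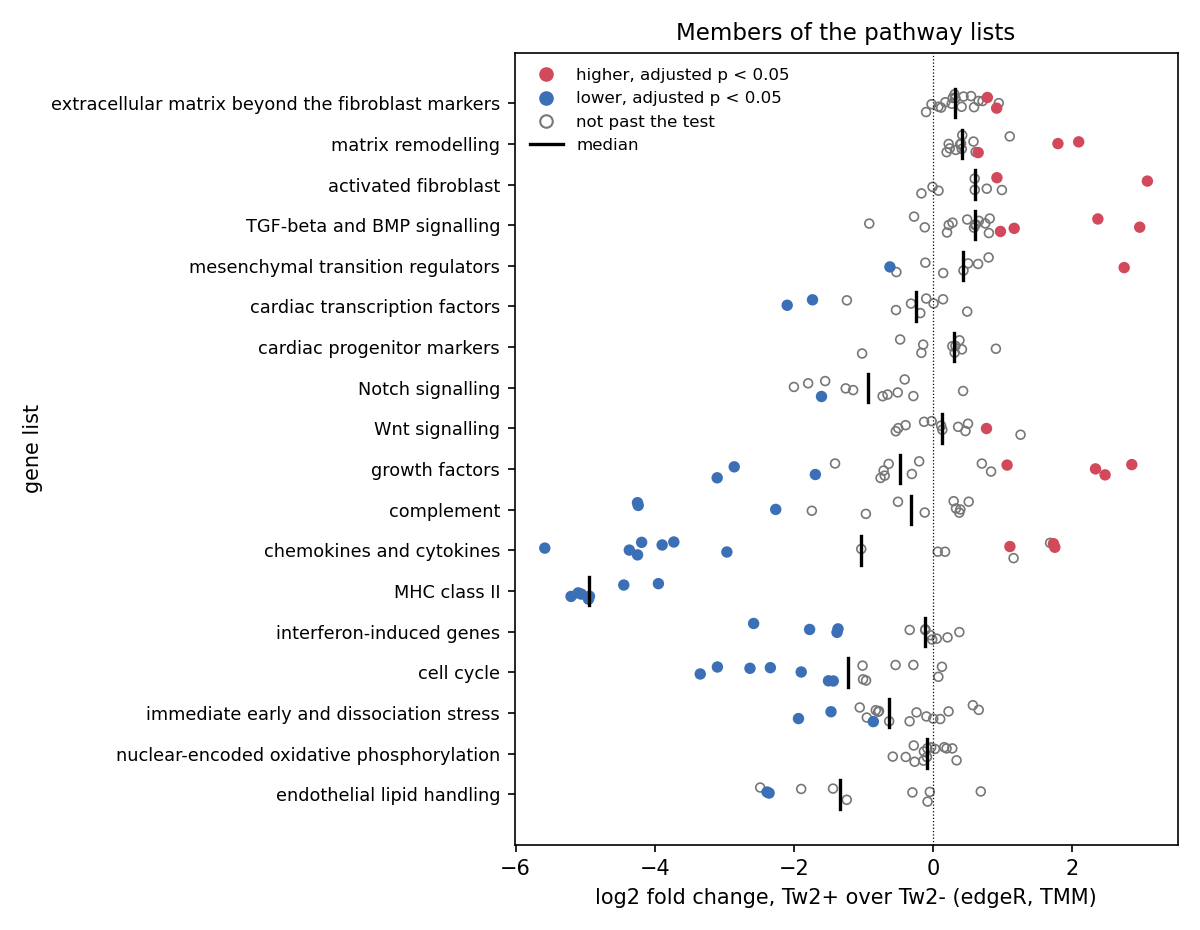
Log2 fold change (Tw2+ over Tw2-, edgeR with TMM) of each tested member of the 18 pathway lists, with filled points for members at an adjusted p under 0.05 and a bar at each list's median. The MHC class II median lies at -4.95 and the TGF-beta and BMP median at 0.61. Scaled to the fibroblast markers, the medians of extracellular matrix (-0.22), matrix remodelling (-0.15), activated fibroblast (-0.04), mesenchymal transition regulators (-0.08), progenitor markers (-0.30) and Wnt signalling (-0.43) lay below 0. The median of all tested genes was -0.59 with that scaling.

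Of the 33 lists, 30 had at least 3 tested members. Camera with its preset correlation called 5 higher and 10 lower. With an estimated correlation 0 of the 15 calls held, and the smallest adjusted p of any of these lists was 0.372. The fry test, which asks whether a list's genes move one way on balance, called 2 lists higher and 9 lower, and its mixed test called 17 lists. DESeq2 called more members than edgeR in several further lists, with 6 of the extracellular matrix, 5 of the remodelling, 7 of the TGF-beta and BMP and 5 of the chemokine and cytokine genes higher, and 6 of the endothelial lipid handling genes lower.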

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

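Scaling to the fibroblast markers, the offset for GC content and length and the fit without both Tw2+ 3 and the unnumbered Tw2- library were chosen after the data were seen, and the other settings before. Without both libraries, 2565 genes were higher and 3068 lower, 1436 and 2493 of them by at least 2-fold, and Twist2 was at 1.41. Scaled to the fibroblast markers, 116 were higher and 3366 lower, 110 and 2873 of them by at least 2-fold, as this scaling shifts all genes down. At an adjusted p under 0.01 the counts were 90 and 701, and 88 and 700 by at least 2-fold. DESeq2 called 1575 higher, and library size alone 404, with 318 by at least 2-fold. With 1 library left out, counts ranged from 81 to 2801 higher and from 811 to 2906 lower, and from 80 to 1440 higher and 810 to 2291 lower by at least 2-fold. The lowest counts came without Tw2- 3 and the highest without Tw2+ 3. Apart from the threshold and the construction of these scalings, the cause was not tested. Of the 2395 calls, DESeq2 shared 2386 of its 3402, limma-voom 2029 of its 2087 and the fit without Tw2+ 3 2384 of its 5707, and 0 shared calls had the opposite sign under any setting.

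The replicate block used only the 4 libraries whose columns carry a number. The labels number every sample, so by elimination each unnumbered column would be the remaining replicate of its group. These columns were not matched to a number, and no block over all 6 libraries was run. The block on 4 libraries gave 1300 genes higher and 2203 lower, with 463 higher by at least 2-fold, and Twist2 at 1.34 with an adjusted p of 0.0136. In camera with the block, the pericyte (adjusted p = 0.0335), interferon (0.0141), endothelial lipid (0.0417) and T and NK cell lists (1.08e-05, with 7 members tested) were lower and the mesenchymal transition list higher (0.0465), while chemokines and cytokines did not pass (0.0824). Of the 10 later lists, the ERK (0.0238), hyaluronan (0.00381) and stroma integrin (0.0261) lists were higher with it. Deviations from the group means correlated at 0.20 for the libraries numbered 2, 0.56 for those numbered 3 and 0.24 for the unnumbered ones, and each library correlated best with its namesake, a hint from the data, as the labels do not say what a number marks.

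Twist2 passed the test in DESeq2 as well (1.00, adjusted p = 0.0333). With 1 library left out it ranged from 0.75 to 1.33, and its adjusted p over all settings ranged from 0.00947 to 0.294. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry called 2 higher. Under the other settings, 4 to 6 lists were higher and 7 to 13 lower. Robust dispersion was not run for the lists. Cd34 (-0.13), Gata4 (-0.077) and Klf4 (-0.30) changed sign relative to the fibroblast markers, and Prox1, at -0.016, ranged from -0.32 to 0.32 with 1 library left out. For the genes named, 2228 of the values under other settings kept direction and side of the threshold, 319 no longer passed, 59 newly passed and 5 changed sign. Of 116 named genes that passed, 56 passed with any library left out, 16 of 50 higher and 40 of 66 lower ones. Depth limits genes near the floor of 0.161 to 0.302 CPM per library, such as Blk.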

Other observations

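The 10 gene lists of the next paragraphs were chosen after the data were seen, as were the tests on the immediate early score and on an even mixture of other cells and all tests that rest on scaling to the fibroblast markers or on the offset for GC content and length. The test on Twist2 read totals and the splits of the libraries were planned. Genes of the integrated stress response, which cells use to cope with amino acid shortage and misfolded protein, were higher in Tw2+ in camera but not in fry. Of 13 genes 8 rose (10 adjusted over the list alone), with a median log2 fold change of 1.75. Asparagine synthetase, Asns, rose by 2.38 (SE 0.47, adjusted p = 0.0111), the amino acid transporter gene Slc7a5 by 2.18 (adjusted p = 0.0220), Sesn2 by 2.06 (adjusted p = 0.0144), the serine synthesis gene Psat1 by 1.91 (adjusted p = 0.0188) and the pseudokinase Trib3 by 1.90 (adjusted p = 0.0134). Atf4, the central factor, was at 0.65 (adjusted p = 0.0763) and Ddit3 at -0.33 (adjusted p = 0.248). Chac1 (3.00, adjusted p = 0.0222), whose rise led to the choice of this list, is not one of the 13. Nor is the stress factor Atf3, which is in the immediate early list and fell past the test. The list was higher in camera at an adjusted p of 0.000616 (adjusted p = 0.407 with an estimated correlation and 0.108 in fry), and relative to the fibroblast markers its median was 1.18, with 4 genes higher and 1 lower. Without Tw2- 3, 0 of the 13 passed in edgeR, without Tw2- 2 4 passed, without the unnumbered Tw2- library 5, without Tw2+ 2 or the unnumbered Tw2+ library 6 and without Tw2+ 3 10. The mean log2 CPM of the list was 5.60 in Tw2+ 3 against 6.58 in Tw2+ 2 and 7.13 in the unnumbered Tw2+ library, and 5.29, 4.93 and 5.46 in Tw2- 2, Tw2- 3 and the unnumbered Tw2- library. Tw2+ 3 also had the highest immediate early score of the Tw2+ libraries. All 6 leukocyte integrins fell (median -4.87, adjusted p = 3.91e-07 in camera, 0.273 with an estimated correlation and 0.00220 in fry). Among them were Itgam (-4.86, with 68.7% of its exonic length under a model on the same strand) and Itgb2 (-4.19).

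Of 8 integrins of stroma, the fibronectin receptor Itga5 (2.12, adjusted p = 0.0152) and Itgav (1.54, adjusted p = 0.0165) rose. Of 11 targets of YAP and serum response factor, Ctgf rose from 1485 to 9393 CPM (2.66, adjusted p = 0.00570), Srf by 1.08 (adjusted p = 0.0234) and Vcl by 0.96 (adjusted p = 0.0485). Of 10 feedback genes of ERK signalling, Fosl1 (2.41, adjusted p = 0.0330), Dusp4 (1.95, adjusted p = 0.0258) and Spry2 (1.16, adjusted p = 0.0152) rose. Genes on the opposite strand overlap 23.2% of the exonic length of Ctgf, 25.5% of Vcl and 57.2% of Fosl1. Of 12 genes of hypoxia and glycolysis, the glucose transporter Slc2a1 (1.61, adjusted p = 0.0350) and hexokinase Hk2 (1.38, adjusted p = 0.0411) rose, while Pfkfb3 (-2.14, adjusted p = 0.00482) and Tpi1 (-0.79, adjusted p = 0.0260) fell. Of 7 hyaluronan and proteoglycan genes the hyaluronan synthase Has1 rose (1.58, adjusted p = 0.0264). Of 6 ligands of the EGF receptor and of the IL-6 family, Areg (-1.97, adjusted p = 0.0298) and Osm (-4.25, adjusted p = 0.000382) fell. This list leaves out ligands of both families whose rise had been seen when it was drawn up, Ereg (2.84, adjusted p = 0.00571), Lif (2.85, adjusted p = 0.00920) and Il11 (2.68, adjusted p = 0.0131), so its falls do not stand for the families. Of 11 semaphorins and receptors, Plxnd1 (-1.48), Nrp2 (-1.14) and Sema7a (-1.65) fell, and 0 of 10 cholesterol synthesis genes passed in edgeR. The mean log2 CPM of the semaphorin list was 5.61 in Tw2+ 3 and 5.45 in the unnumbered Tw2- library. The vascular endothelial markers had the same order in these libraries, and their median was -2.19. In camera on all 6 libraries with TMM and the filter on low counts, the adjusted p was 0.0942 (integrins of stroma), 0.323 (YAP), 0.0571 (ERK), 0.808 (hypoxia), 0.0550 (hyaluronan), 0.608 (ligands), 0.551 (semaphorins) and 0.696 (cholesterol). In fry, the ERK (adjusted p = 0.0155), stroma integrin (0.0161), hyaluronan (0.0246) and YAP (0.0414) lists were higher, while in camera with an estimated correlation the adjusted p was 0.273 for the first 3 and 0.407 for YAP. In camera the ERK list passed with library size alone (adjusted p = 0.0121), upper-quartile factors (0.0415), no filter on low counts (0.0416) and the offset for GC content and length (0.0490), and without Tw2- 2 (0.0337), Tw2- 3 (0.0356), Tw2+ 2 (0.0342) or the unnumbered Tw2+ library (0.0367). The hyaluronan list passed with library size alone (0.0265), upper-quartile factors (0.0432) and the offset (0.0480), and without Tw2- 3 (0.0356), the unnumbered Tw2- library (0.0284) or the unnumbered Tw2+ library (0.0127), and the stroma integrins without the last of these (0.0367). Relative to the fibroblast markers the ERK (adjusted p = 0.00273, median 0.39) and hyaluronan (adjusted p = 0.0253, median -0.11) lists ranked above the other genes in camera, with 0 members of either called higher in edgeR. With 1 library left out, Ctgf, Pfkfb3, Osm, Ereg and Lif passed in all 6 fits, Asns, Trib3 and Il11 in 5, Itga5, Spry2, Sesn2 and Psat1 in 4, Itgav and Areg in 3, Tpi1, Vcl, Slc2a1 and Chac1 in 1 and Slc7a5, Srf, Dusp4, Fosl1, Hk2, Has1, Plxnd1, Nrp2 and Sema7a in 2, while Itgam and Itgb2 passed in all 6.

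The 698 genes higher in Tw2+ by at least 2-fold were set against 3 technical explanations. A bias of GC content or gene length is argued against, since 94.7% of them (661) stayed at 2-fold or more with an offset for both. An equal rise of all fibroblast transcripts, from a larger share of fibroblast RNA, is argued against for 110 genes that were higher by at least 2-fold relative to the fibroblast markers, where 5.8 false calls are allowed. These are 15.8% of the 698, and for the other 588 such a rise and a change in the cells cannot be told apart. Scaling to the markers lowered the median log2 change of the 588 from 1.37 (median SE 0.34) to 0.74 (median SE 0.38), which ended the call of 582. Handling cannot be told apart from a change in the cells. A fit of all tested genes with the immediate early score beside the group called 100 genes higher by at least 2-fold, where 8 false calls are allowed. Of the 698, 95 are among them. For the other 603 the median log2 change fell from 1.39 (median SE 0.34) to 0.75 (median SE 0.25) in that fit, which ended their calls at 2-fold or more. A linear dependence on the score, as fitted, does not account for the 100 genes. The fit cannot decide on handling, since handling that differed between the sorted populations would be carried by the group itself. The slope on the score also rests mostly on Tw2+ 3, with a score of 10.8 against 9.65 in Tw2+ 2 and 9.67 in the unnumbered Tw2+ library. Within the groups the mean of the 698 had a slope of -0.95 on the score, at a permutation p of 0.0556 where the smallest possible is 0.0278. The identity of the sorted cells, which the design names, stays open and may account for both parts.

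Leukocyte and endothelial markers were both lower in Tw2+. A single even mixture of other cells in Tw2- would lower every marker alike if the marked cells held none of these transcripts themselves. On that condition it is argued against by a macrophage score that fell further than the endothelial one. The difference was -2.07 (SE 0.48), and from -2.31 to -1.70 with 1 library left out. The scores cannot tell an uneven mixture from endothelial transcripts within the marked cells. The macrophage score differed by -4.20 (SE 0.47), the endothelial by -2.13 (SE 0.89) and the cardiomyocyte score by -2.10 (SE 0.51). Bias of GC content or length is argued against as well, since at least 97.3% of both medians remained with the offset. Unequal depletion of cell types by the tdTomato sort, and endothelial RNA or cells in Tw2+ 3, whose endothelial score lay above that of the unnumbered Tw2- library, may contribute and were not tested.

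The Twist2 transcript differed by about 2-fold between cells sorted by a Twist2 driver. Too few reads for a larger fold to be seen is argued against by the ratio of read totals, 2.07 with an upper 95% Poisson bound of 2.55, below the 4-fold difference tested. Relative to the fibroblast markers the log2 fold change was 0.46 (SE 0.32, adjusted p = 0.294, against 0.00947 to 0.294 over all settings). Its SE is too wide to tell no change from the unscaled log2 fold change of 1.00. Whether the Twist2 level follows the share of fibroblast RNA is therefore undecided. Reads of the antisense gene Gm29100 and marked cells that no longer express Twist2 stay open and were not tested.

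The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 976 genes higher and 1419 lower, 698 and 1277 by at least 2-fold, and was 1 of the 10 in each case, with 0 as the highest other count for all 4. For lists it gave 5 higher and 10 lower, and since a split and its mirror are the same, each other split was counted in the direction with more lists. On that count 8 of the 10 splits reached 5 and 3 reached 10, with 13 as the highest other value.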
